A study of Mus musculus with 4 samples.

How the data were processed

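Gene expression was measured on 4 two-colour cDNA microarrays of mouse cells. NIH3T3 is an established mouse embryonic fibroblast line. Each array set RNA of an NIH3T3 line transfected with Erbb2, which encodes a receptor tyrosine kinase, against RNA of untransfected NIH3T3 cells. Per the labels, the transfected sample carried Cy5 on arrays 1 and 2 and Cy3 on arrays 3 and 4, so each dye orientation had 2 arrays. The series design calls the arrays technical replicates. There was thus 1 biological sample per line, and no p-value here measures the spread between independent cultures or transfections. The p-values of single genes measure the spread between arrays. Those of gene lists set the list's genes against all other genes, and genes are not independent replicates. Per the labels' protocols, total RNA was purified on silica columns and reverse transcribed, and the cDNA was labelled indirectly with the dyes. Part of that protocol text speaks of organs and of pooled control animals, which does not describe a cell line, so it was not taken to describe these samples in detail.

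The values deposited by the authors are log2 ratios of both channels plus a constant that differs from array to array. Image analysis software, background correction and normalization are not given in the sources used here. The scale was read from the values: the commonest values of an array lie exactly 1 unit apart, as ratios of 1:1 and 1:2 do on a log2 scale. The largest values lie 16.61 units from the value of a 1:1 ratio, which is log2 of 100000 and was taken as a cap on ratios with an empty denominator. Array medians were 0.139, 0.031, -0.177 and -0.229 for arrays 1 to 4, so the arrays were not centred on their medians. The direction of the ratio is not stated. Capped ratios lie above 0 on arrays 1 and 2 and below 0 on arrays 3 and 4, which means that the sign of 1 orientation had been turned. With the customary quotient of Cy5 over Cy3 and the transfected sample as channel 1 on every array, the likely direction is transfected over untransfected. All signs in the text rest on that reading, and all would turn together if it were wrong.

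Capped ratios (63, 120, 121 and 114 on arrays 1 to 4) were set to missing. Of 20355 probes, 14030 had exactly 1 gene symbol in the platform annotation, 5 had several and 6320 were unnamed here. Of the probes with 1 symbol, 13994 were matched to a RefSeq gene table (assembly GRCm38.p6) by gene identifier, which changed 0 symbols. No coordinates are given, because no build is named for the array.

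The columns were then compared row by row, across probes, which are not independent replicates, after each array had been centred and scaled by its median absolute deviation and extreme values had been limited. In the first 6000 rows, the mean Pearson correlation of array 1 with arrays 2 to 4 was 0.12, and it was highest with the rows as they stand, as also in 5 of 6 windows of 1000 rows. Between rows 8000 and 18000 it was -0.002 as the rows stand and 0.081 when arrays 2 to 4 were read 3 rows higher than array 1. In the last part of the table it was -0.009 as the rows stand and 0.149 with an offset of 4 rows. Arrays 2 to 4 lined up with one another without an offset in all 20 windows of 1000 rows. Probe pairs of the same gene, compared within 1 array, were compared as a separate check of the names. In the first 6000 rows such pairs had r = 0.271, 0.151, 0.004 and 0.188 on arrays 1 to 4 without an offset, so they gave no support for the names of array 3 there, which rest on the correlation of array 3 with the other arrays (0.101, 0.076 and 0.185 with arrays 1, 2 and 4). Between rows 8000 and 18000 the pairs had r = 0.115 on array 1 without an offset, and 0.058, 0.121 and 0.13 on arrays 2 to 4 with an offset of 3 rows. In the last part of the table such pairs had r = 0.304 on array 1 without an offset, and 0.216, 0.208 and 0.215 on arrays 2 to 4 with an offset of 4 rows. All 4 columns of the table used here thus lined up with one another only in its first 6000 rows, which are 29.5% of all rows, and tests were run on those rows. A table in which arrays 2 to 4 were moved back by 3 and 4 rows was analysed as an alternative, leaving out 2300 rows in which the offset was unclear; this choice was made after the data were seen.

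Probes of a gene were averaged on each array, and genes measured on all 4 arrays were tested with limma (lmFit and eBayes) on the log2 ratios. The model held the mean over both dye orientations and a dye term coded 1 and -1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Shifts of gene lists were tested with camera in limma, with its preset correlation of 0.01 between genes and again with an estimated correlation. With the estimated correlation, camera's test has only the few degrees of freedom that 4 arrays leave after both model terms. Small p-values are then hard to reach. A call lost there cannot tell correlation between genes from a lack of arrays. Before the data were examined, 24 lists were fixed, 18 of pathways and 6 of markers of other cell types, and lists with at least 5 measured members were tested. As camera compares a list with all other genes, a shift is relative to them. The place of a list's median among 10000 random lists of the same size was also taken, without matching on intensity, since ratios hold none. The rule for naming genes, also fixed before, took called genes with 1 sign on all arrays, up to 12 per sign, and up to 4 called members per list. As no gene was called, it took the 8 genes of each sign with the largest mean and 1 sign on all arrays, as values and not as calls. Members of shifted lists and some further genes are named to describe their lists and were chosen after their values were seen.

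On data simulated for the 2238 genes of the first rows, with 200 of them changed, the test called 1.1% of the genes changed by 1 log2 unit, 45.0% of those changed by 2 and 92.8% of those changed by 4. With 20 genes changed by 3 log2 units it called 2.5%, and 18 of 20 simulated data sets gave no call at all. With few changed genes, most large changes were therefore not called in this design. Camera was tried on simulated independent genes without a dye effect, at an unadjusted p under 0.05. It found a list of 25 genes shifted by -0.8 log2 units in 50 of 50 runs and an unshifted one in 1 of 50. These rates do not cover correlated genes or the adjustment over all lists. The lists tested in the first rows had 5 to 20 members, and lists of that size were not simulated. Alternatives covered the dye term, centring, scaling, robust variances, single probes, missing values, a fold threshold, leaving out each array, the estimated correlation, the choice of rows and the capped ratios. A fit without 1 array tested all genes with a value on the remaining arrays (2301 to 2709 genes). It thus took in genes missing on the array left out, and list members changed. Its mean weighed both dye orientations equally, so the lone array of 1 orientation counted as much as both arrays of the other. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.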

Results

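The series asked which genes differ in expression between NIH3T3 mouse fibroblasts transfected with Erbb2 and untransfected NIH3T3 cells. Erbb2 encodes a receptor tyrosine kinase of the epidermal growth factor receptor family. RNA of both lines was compared on 4 two-colour arrays, with the dyes swapped on 2 of them. Of 20355 spots, 94.6%, 81.0%, 76.8% and 89.4% had a value on arrays 1 to 4. Below, a gene is called lower or higher in the transfected line, which is the likely but unstated direction of the deposited log2 ratios. Values are means ± SD over the 4 arrays, which are repeated hybridisations of 1 sample per line. Errors and the p-values of single genes thus cover the spread between arrays only. The p-values of gene lists set genes against genes, and no p-value covers the spread between cultures.

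**Figure D1:**
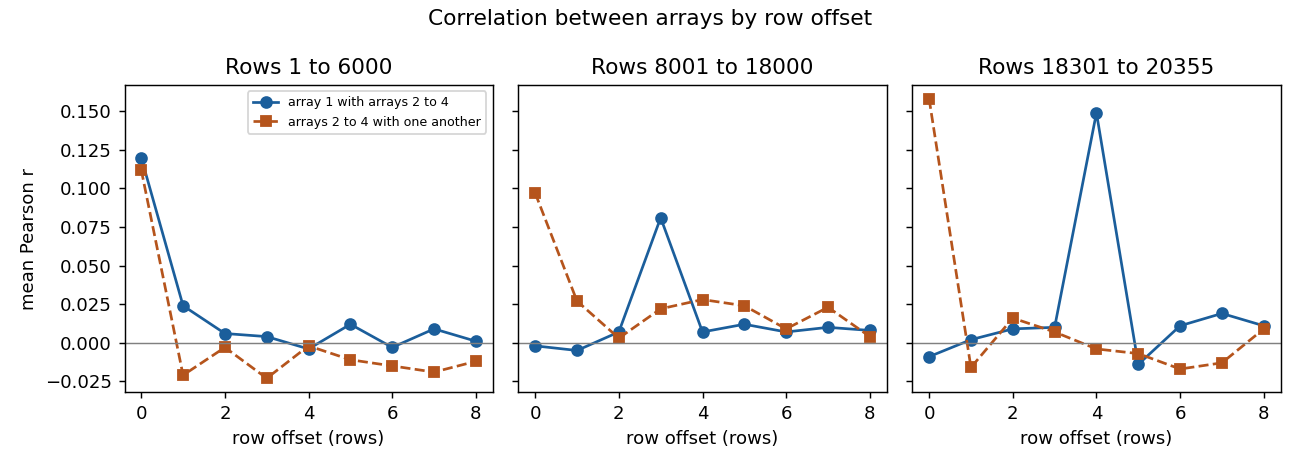
Mean Pearson correlation across probes (vertical axis) against the number of rows by which 1 column is read higher than the other (horizontal axis), for the first, middle and last part of the table. Array 1 correlated best with arrays 2 to 4 at an offset of 0 in the first part (0.12), of 3 rows in the middle part (0.081) and of 4 rows in the last part (0.149), while arrays 2 to 4 correlated best with one another at 0 throughout.

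The columns of all 4 arrays lined up with one another only in the first 6000 rows of the table, and 2238 genes with a value on every array were tested there. No probe was named for Erbb2, so the level of the transfected gene was not analysed here and the labels were not checked by it. Across these genes, which are not independent replicates, the ratios of 2 arrays correlated weakly, with Pearson's r between 0.108 and 0.219 and Spearman's coefficient between 0.066 and 0.209 over the pairs of arrays. The arrays of 1 dye orientation gave r of 0.219 (arrays 1 and 2) and 0.177 (arrays 3 and 4). A total of 513 genes (22.9%) had the same sign on all 4 arrays, where chance gives 12.5%. With the signs of arrays 3 and 4 turned, 289 genes had 1 sign.

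The genes furthest below 0 in the transfected line included several that encode matrix proteins. Col1a1, which encodes a chain of type I collagen, had a mean log2 ratio of -4.91 ± 1.46. Fn1, which encodes fibronectin, had -4.19 ± 0.13, an 18.3-fold lower level with little spread between arrays. Fbln2 (fibulin 2) had -3.27 ± 0.51 and Sparc, a collagen-binding matrix glycoprotein, had -3.16 ± 0.35. Timp3, an inhibitor of matrix metalloproteinases, had -3.97 ± 1.33. The retinoic acid hydroxylase gene Cyp26b1 had -3.57 ± 2.14, the prostacyclin synthase gene Ptgis -3.08 ± 1.18, and Arhgap31 -3.37 ± 2.12. Arhgap31 differed between the dye orientations, with means of -5.18 (transfected sample in Cy5) and -1.55 (in Cy3).

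On the higher side, the largest mean belonged to Serpina12, which encodes the adipokine vaspin, at 3.67 ± 0.57, a 12.7-fold higher level. The transcription factor gene Klf5 had 2.40 ± 0.26, with means of 2.40 in both dye orientations. The transmembrane glycoprotein gene Gpnmb had 2.20 ± 0.32, the metalloproteinase gene Adam19 2.13 ± 0.47 and the cGMP-dependent protein kinase gene Prkg2 2.10 ± 0.62. Glod5 (2.19 ± 1.18), Ascc2 (1.98 ± 1.41) and Layn, which encodes a hyaluronan-binding membrane protein (2.36 ± 2.59), varied more between arrays, and the SD of Layn exceeded its mean. Layn had a fitted mean, with both dye orientations weighed equally, of 1.031 without array 4 and 3.692 without array 3. With rows moved back its mean was 1.251.

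**Figure D2:**
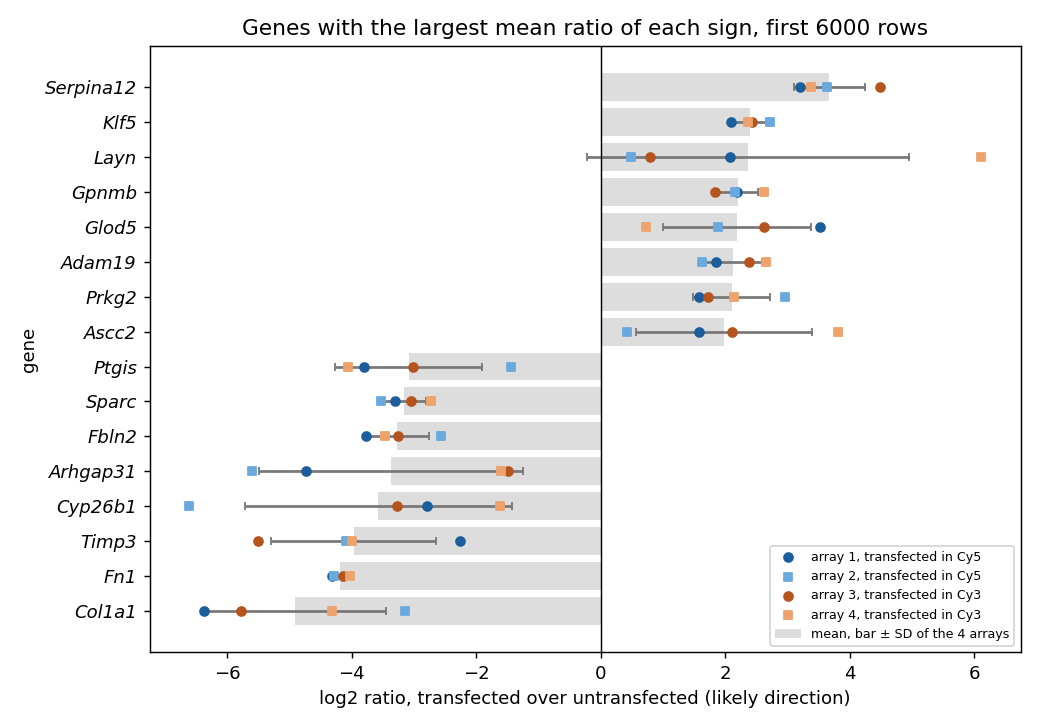
Log2 ratio, transfected over untransfected in the likely direction (horizontal axis), of the 8 genes with the largest mean ratio of each sign among genes with 1 sign on all 4 arrays (vertical axis). Points are single arrays, grey bars the means and error bars the SD over the 4 arrays; Fn1 spread by 0.13 and Layn by 2.59 around means of -4.19 and 2.36.

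None of these genes passed the test over all genes. Limma called 0 of the 2238 genes, and the smallest adjusted p was 0.0718, for Fn1. Serpina12, Sparc and Arhgap31 each had 0.0837. For Arhgap31 the dye term took up the difference between the orientations, and limma's adjusted p without that term was 0.243. At an unadjusted p under 0.05 there were 276 genes, of which 217 were lower and 59 higher, where chance gives 111.9. The median of all genes was -0.173; after centring each array on its median, 161 genes were lower and 100 higher at that level. Without the dye term limma called 5 genes, namely Fn1 (adjusted p = 0.0136), Sparc and Serpina12 (0.0364 each), Fbln2 (0.0375) and Igfbp4 (0.04).

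Extracellular matrix genes were lower as a group. The 11 measured members of the list had a mean log2 ratio of -2.12 ± 0.22 over the 4 arrays, against the median of -0.173 of all genes. The shift passed camera's test (adjusted p = 2.46e-07 over 16 lists, lower on 4 of 4 arrays) with its preset correlation. It did not pass with an estimated correlation (adjusted p = 0.433, unadjusted p = 0.0271). The latter test had few degrees of freedom, so the lost call does not tell whether correlation between the genes matters. Over all genes 0 members were called; adjusted over the list alone 7 passed, all with a mean below 0. These were the collagen genes Col1a1, Col5a2 (-1.64 ± 0.96) and Col6a1 (-1.71 ± 1.27), together with Fn1, Fbln2, Sparc and the procollagen C-proteinase enhancer gene Pcolce (-1.36 ± 0.58). Tnc, which encodes tenascin C, had -0.46 ± 0.50 and Col11a1 -0.18 ± 0.89. Of 10000 random lists of 11 genes, 0 had a median as low as that of the list (-1.64).

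Lists of insulin-like growth factor and TGF-beta genes and of angiogenesis factors were lower by less. The 8 members of the former had a mean of -0.94 ± 0.15 (camera, adjusted p = 0.021, and adjusted p = 0.506 with an estimated correlation), and 6 of them were below 0 on every array. Adjusted over the list alone, Igfbp4 (-2.72 ± 0.27) and Igfbp6 (-1.28 ± 0.36), which encode binding proteins of insulin-like growth factors, passed, and over all genes 0 passed. Igf1r had -0.90 ± 0.51, Tgfbr2 -1.19 ± 0.79 and Irs1 0.24 ± 0.11. The 10 members of the angiogenesis list had a mean of -0.98 ± 0.30 (camera, adjusted p = 0.021, and adjusted p = 0.506 with an estimated correlation). Of these members, 4 were below 0 on every array and 6 had mixed signs. Adjusted over the list alone, 1 member passed: Ccn1, which encodes a matricellular protein, with -2.35 ± 1.87. Its mean was larger in size with the transfected sample in Cy5 (-3.89) than in Cy3 (-0.81). Ccn2 had -1.72 ± 1.24, and Nrp2 -0.12 ± 0.51. The growth factor list lost its call without array 3 (adjusted p = 0.111) or array 4 (0.134). The angiogenesis list lost it without array 2 (0.07), array 3 (0.0571) or array 4 (0.134). These fits also took in genes missing on the array left out, so list members changed. On the members described here, array 3 had the mean nearest to 0 in both lists (growth factor -0.726, angiogenesis -0.614). Without array 3 both means still moved towards 0 (-0.705 and -0.908), through the genes that joined. The lost calls thus cannot be credited to the array left out alone.

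**Figure D3:**
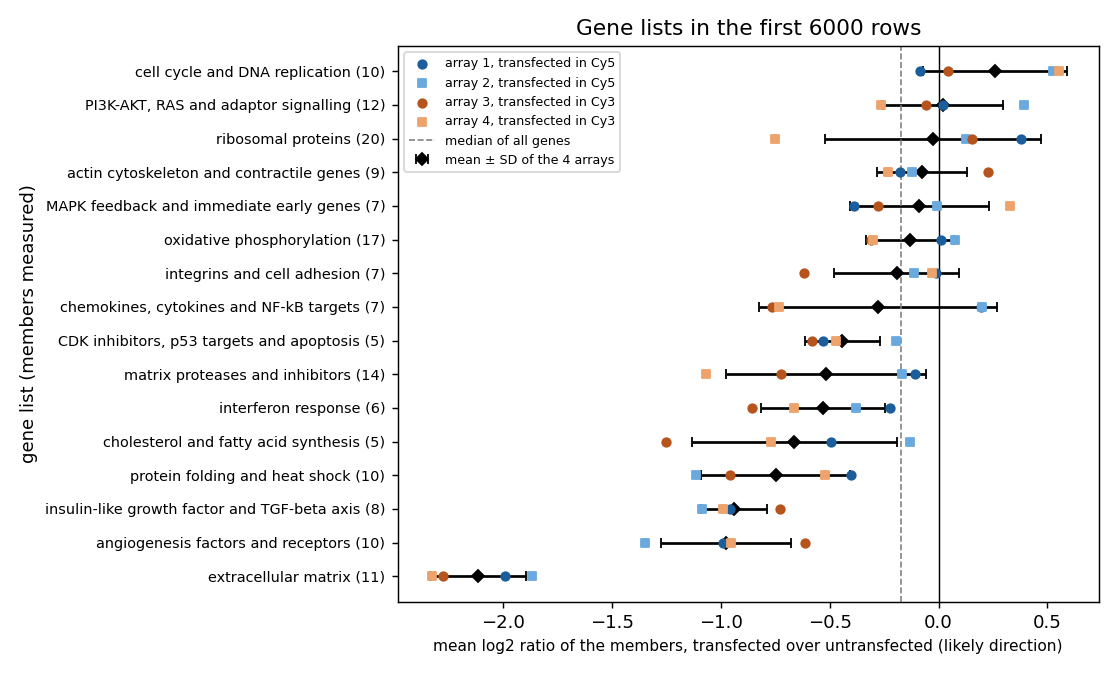
Mean log2 ratio of the measured members of each gene list (horizontal axis, transfected over untransfected in the likely direction) for the 16 lists tested (vertical axis, number of members in brackets). Coloured points are single arrays, black diamonds with bars the mean ± SD over the 4 arrays, and the dashed line is the median of all genes at -0.173; the extracellular matrix list lies at -2.12 ± 0.22.

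The other 13 lists did not pass camera. Cell cycle and DNA replication genes came closest, with a mean of 0.26 ± 0.33 over 10 members (adjusted p = 0.0587); Top2a had 0.77 ± 0.33, Cks1b 0.91 ± 0.34 and Pcna -0.08 ± 1.10. This list passed without the dye term (0.0426), with every probe on its own (0.0338) and without array 1 (0.0387), where its mean was 0.41, against 0.09 without array 2 and 0.13 without array 4. With an estimated correlation its adjusted p = 0.773. Protein folding and heat shock genes had a mean of -0.75 ± 0.34 (adjusted p = 0.202; 0.0075 in the first 4000 rows alone, with a mean of -1.21), and 3 of 10 members passed when adjusted over the list alone: the small heat shock protein gene Cryab (-1.94 ± 0.48), the stress-induced Ddit4 (-1.68 ± 0.11) and the disulphide isomerase gene Pdia4 (-1.54 ± 0.75). Matrix proteases and inhibitors had a mean of -0.52 ± 0.46 (adjusted p = 0.59), with Timp3 and Adam19 passing on opposite sides when adjusted over the list alone; without array 4 the mean was -0.182. Interferon response genes had -0.53 ± 0.28 (0.383), with H2-K1 and Ifitm1 passing when adjusted over the list alone. MAPK feedback and immediate early genes had -0.09 ± 0.32 (0.726); Fosl1, which encodes a subunit of AP-1, had 1.25 ± 0.32 and Klf4 -1.86 ± 1.55. Cholesterol and fatty acid synthesis genes had -0.66 ± 0.47 (0.59). Genes of CDK inhibitors, p53 targets and apoptosis had -0.44 ± 0.17 (0.59), but -0.068 without array 2, where camera's direction turned. Chemokines, cytokines and NF-kB targets had -0.28 ± 0.55 (0.756), integrins and cell adhesion genes -0.19 ± 0.29 (0.765), and oxidative phosphorylation genes -0.13 ± 0.20 (0.756). Actin cytoskeleton genes had -0.08 ± 0.21 (0.749), ribosomal protein genes -0.02 ± 0.50 (0.59), and PI3K-AKT, RAS and adaptor genes 0.02 ± 0.28 (0.59). Leaving out 1 array turned the sign of the MAPK, integrin, actin, ribosomal and PI3K-AKT means. Without array 2 the chemokine mean was -0.107 and the oxidative phosphorylation mean -0.06. A fit without 1 array also took in genes missing on that array, so list members changed. The moves given here thus cannot be credited to the array left out alone. The ERBB receptor and ligand list had 0 measured members, and the glycolysis list had 3.

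With arrays 2 to 4 moved back to match array 1 in the lower rows, 6327 genes were tested. Limma called 0 of them (smallest adjusted p = 0.105), with 730 genes at an unadjusted p under 0.05. Without the dye term limma called 6 of them (smallest adjusted p = 0.0398). Matrix genes again stood out. The collagen cross-linking enzyme gene Lox had -5.18 ± 0.95, Col1a2 -3.36 ± 0.69 and the proteoglycan gene Bgn -5.48 ± 3.13. The extracellular matrix list, now with 20 members, had a mean of -1.85 ± 0.26 (camera, adjusted p = 3.67e-08 over 21 lists; adjusted p = 0.47 with an estimated correlation), and 11 members passed when adjusted over the list alone. Of the 20 members, 18 had a mean below 0, and 11 were below 0 on every array. Col3a1 had a mean above 0 (0.89 ± 1.36), and Col4a1 (-0.18 ± 0.24) and Fbln1 (-0.10 ± 1.21) had means near 0. In the lower rows by themselves the list had a mean of -1.79 after the move (adjusted p = 8.15e-04, and adjusted p = 0.787 with an estimated correlation) and -0.31 as deposited (adjusted p = 0.958). Its 6 members with no probe in the first rows had a mean of -0.82 and did not pass (adjusted p = 0.825). The growth factor and angiogenesis lists both missed the threshold in the larger table, each at an adjusted p of 0.0568. That table holds the first rows again. In the lower rows by themselves, after the move, the angiogenesis list had a mean of 0.052 (adjusted p = 0.913) and the growth factor list -0.398 (adjusted p = 0.401). The growth factor genes with no probe in the first rows had a mean of 0.052 (adjusted p = 0.825).

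Markers of other cell types were too few for a test in the first rows. In the larger table, those of macrophages and other leukocytes had a mean of 0.29 ± 0.73 (7 members, adjusted p = 0.45), of adipocytes 0.30 ± 0.75 (6 members, 0.743), of endothelial cells -0.21 ± 0.70 (5 members, 0.943) and of muscle cells -0.12 ± 0.21 (8 members, 0.943). None passed camera. Epithelial and hepatocyte markers had 3 measured members each. Of the former, Cldn3 had 0.86 ± 1.0, Krt8 0.35 ± 0.73 and Epcam -0.52 ± 0.33, and Epcam had -1.09 ± 0.70 in the first rows. Of the latter, Apoa1 had -0.83 ± 0.56, Apoa2 -0.73 ± 0.76 and Ttr -0.19 ± 1.25. Of the ERBB receptors and ligands 2 were measured, Egfr at -0.07 ± 1.26 and Hbegf at 0.53 ± 1.34, both with an SD above the mean. The glycolysis list, with 12 members, had -0.26 ± 0.14 (adjusted p = 0.496).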

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

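All tests in this part were chosen after the result was seen. Of 91 values checked, 7 had 1 array far from the other 3. The nominal count of 4.55 assumes independent and unselected values. Here many genes had been picked for a large mean. List means were checked in the first rows and again in the larger table, which holds those rows. The counts thus cannot be set against chance. With the lower rows moved back, Pdpn lay at 6.48 on array 3 and near 1.1 to 1.3 elsewhere (gap over range 0.961), and Ryr1 at 6.52 on array 4 (0.837). The integrin and cell adhesion list mean had an outlying array in the first rows (0.834) and in the larger table (0.902). In the first rows, Col5a2 lay at -0.21 on array 2 and near -2.1 on the others (0.931), Col11a1 at -1.51 on array 2 (0.857) and Fgfr1 at -3.23 on array 2 (0.925).

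The loss of agreement between array 1 and the other arrays below the first 6000 rows was weighed as a technical pattern; no biological explanation was tested. Noisier spots further down the table were argued against, since arrays 2 to 4 kept a mean r of 0.158 with one another in the last part. Unrelated RNA on array 1 was argued against too, since array 1 reached a mean r of 0.149 with the others at an offset of 4 rows. A slip of the rows of arrays 2 to 4 against the probe names may account for the pattern: probe pairs of the same gene on these arrays had a mean r of 0.213 at that offset. The step at which the rows slipped stays open.

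The lower ratios of extracellular matrix genes were weighed next. Dye bias alone would give opposite signs in both orientations, whereas the list mean was -1.93 in the orientation with the smaller change and -2.30 in the other. An offset of whole arrays was argued against by the distance of -1.94 between the list mean and the median of all genes, with an SD of 0.22 over arrays. Wrong names of single probes stay open for most members: only 3 had other probes in the lower rows, with a mean of -2.07 after the move, and of these Fn1 (-3.44) and Sparc (-3.13) were low again while Loxl1 was not (0.36). With 1 biological sample per line, an effect of Erbb2 and any other difference between both lines cannot be told apart.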

How the results depend on the processing

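The choices of rows and the capped ratios were added after the data were seen; the other alternatives were planned. Limma's count of 0 genes became 5 without the dye term, 4 with arrays scaled to a common spread, 2 (Fn1 and Col1a1) with every probe on its own and 1 (Fn1) in the first 4000 rows. The count stayed at 0 under centring, robust variances, a minimum of 3 arrays, without any 1 array, with all rows as deposited, with rows moved back and with capped ratios kept. A 1.5-fold threshold cannot add to 0 calls. Genes at an unadjusted p under 0.05 numbered 155 without array 2 (main count 276). The causes were not tested. The 16 named genes kept their sign in all 237 values under other settings. They had been chosen for 1 sign on all 4 arrays, which largely fixed this outcome, so it is no sign of robustness.

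The 3 list shifts became 0 with an estimated correlation, where camera had few degrees of freedom. There was 1 with rows moved back, 1 in the lower rows moved back, 0 in those as deposited and 0 without genes of the first rows. Leaving out 1 array, which also changed list members, gave 1 to 4. The count was 4 without the dye term and with every probe on its own, where cell cycle genes passed as well (means 0.26 and 0.30); they also passed without array 1 (0.41). Protein folding genes passed in the first 4000 rows (-1.21). The extracellular matrix list lost its call with an estimated correlation (mean -2.12), in the lower rows as deposited (-0.31) and in their genes absent from the first rows (-0.82). Without any 1 array it kept its call, with means from -2.31 to -1.80. With all rows as deposited it also kept its call, but its mean was -1.10. The growth factor list kept its call in that setting too, with a mean of -0.69. Its adjusted p from camera was 0.00802 there, against 0.021 in the main test. In the lower rows of that setting the columns did not line up, so this call is no support for the list. The angiogenesis list had -0.98 with an estimated correlation, -0.56 with all rows as deposited, -0.65 with rows moved back, -0.043 in the lower rows as deposited and 0.052, the opposite sign, in the lower rows moved back; leaving out 1 array gave -0.97 to -0.80. The growth factor list had -0.94 with an estimated correlation, -0.58 with rows moved back, -0.69 in the first 4000 rows, -0.40 and -0.63 in the lower rows moved back and as deposited, and 0.052, the opposite sign, in genes absent from the first rows; leaving out 1 array gave -0.98 to -0.71. The causes were not tested.

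The mean correlation between arrays was 0.149, and 0.088 with all rows as deposited and 0.063 with capped ratios kept. Alternatives for Erbb2 gave no value, as no probe was named for it. Each array paired both samples, and the tested log2 ratios hold that pairing, so no separate paired analysis was run. Intensities were not used here, so signal over background was not assessed.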

Other observations

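The comparisons of endoplasmic reticulum members of the protein folding list were chosen after the values were seen. So were the genes named here and the move of the lower rows. The fit of genes measured on at least 3 arrays was planned. Several genes missing on 1 array had large ratios on the other 3 in the first rows. Lox had -5.25 ± 0.70, Fbln5, which encodes an elastic fibre protein, -4.50 ± 0.59, Col1a2 -3.63 ± 0.19 and the transcription factor gene Atoh8 -4.76 ± 0.27 (SD, 3 arrays); Adam8 had 3.36 ± 1.14. None was called (adjusted p = 0.204 for Lox and Atoh8). With the lower rows moved back, Id3, an inhibitor of DNA binding downstream of TGF-beta family signals, had -2.002 ± 0.546, Cd44, a hyaluronan receptor, 1.37 ± 0.69 and Birc5, which encodes survivin, 1.45 ± 0.91 over 4 arrays, also without a call.

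Endoplasmic reticulum members of the protein folding list, not all of them chaperones, were on average low on arrays 2 to 4 and less so on array 1. In the larger table, the 9 such members of the protein folding list had means of -0.55, -1.53, -1.85 and -1.39 on arrays 1 to 4; Hspa5 (BiP) had -0.14 on array 1 and -2.33, -1.98 and -2.23 on the others. Of the 9 members, 7 were below 0 on each of arrays 2 to 4, as were 5 of the 18 outside the endoplasmic reticulum. Dnajb11, of the 9, was lower on array 1 (-1.254) than on the others (-0.398, -0.808 and -0.668). Ddit3, outside the set, had 0.952 on array 1 and -2.789, -3.535 and -3.224 on the others. The pattern was thus neither shared by all 9 nor limited to them. The whole list missed camera's threshold (adjusted p = 0.0568). Over arrays 2 to 4 the 18 members outside the endoplasmic reticulum had a mean of -0.40. A two-sided permutation p of 0.0229 between both sets was computed on the values that had prompted the split, so it does not decide whether the whole list shares the change. Generally weaker ratios on array 1 stay open. Its extracellular matrix mean was 1.02 times that of arrays 2 to 4, but that is 1 list with large changes. The SD of all ratios was smallest on array 1 (0.973, against 1.455, 1.564 and 1.211 on arrays 2 to 4). Another RNA preparation on array 1 may account for the difference of 1.035 log2 units between it and the others; with 1 such array and a design that speaks of technical replicates this stays open, and a repeat array would be needed.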
